A study of Drosophila melanogaster with 2 samples.

How the data were processed

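Chromatin immunoprecipitation with an anti-GFP antibody was followed by sequencing in whole Drosophila melanogaster embryos, 0 to 18 h old, of a strain with an eGFP-tagged copy of giant (gt), per the labels. Chromatin was sonicated to 200 to 800 bp, per the labels. The series holds 1 group with 2 biological replicates, so no treated and control groups were compared.

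The authors called peaks on the dm6 assembly against a control library, per the labels and the text files deposited with the samples. The aligner and the peak caller are not given in the sources used here. The authors deposited 8 peak lists: a long ranked list and a short thresholded list for each replicate, and 2 ranked and 2 thresholded lists for the series. The peak signal is the deposited value of the authors' caller, and its scaling is not given in the sources used here. The score column of the deposited lists is capped and follows the irreproducible discovery rate (IDR), a measure of how far 2 peak sets rank a region alike. The −log10 column of the deposited ranked lists holds the global IDR. Each thresholded list was checked against its ranked list: every thresholded peak had a −log10 IDR of at least 2, and 114 pooled regions past that value were left out by the authors. In 1 of the series-level ranked lists, 67.6% of the first and 83.2% of the second paired regions were found among the replicates' own regions, and in the other 0%. The first list was therefore used for the correlation between replicates, without assigning either column to a replicate. The longer thresholded series-level list is called the pooled list below, and the shorter one the conservative list. Signals were used to rank, filter or describe peaks within a list, and to correlate ranks between the replicates. Around gt, median signals were also compared with random windows of the same replicate's list. The files hold no read counts, so sequencing depth is unknown and intervals cover only the sampling of peaks.

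Peaks on chromosome arms 2L, 2R, 3L, 3R, 4 and X were analysed with the Release 6 genome sequence, which is the assembly of the files, and Ensembl release 115 genes. The 24 gene lists, the motifs and the tests were set before the data were examined, except where stated, and 7 symbols in the lists were matched through current names. A summit was called promoter within 500 bp of a protein-coding transcription start site (TSS), then 5' UTR, CDS, 3' UTR, other exon, intron or intergenic, in that order. Shares were compared with 1000 random placements on the same arms (two-sided permutation test, Benjamini-Hochberg over the classes). A peak was assigned to the protein-coding gene with the nearest TSS, at most 10000 bp away. The number of genes with a peak in each list was compared with 10000 random lists matched on 10 classes of the length of sequence nearest to each gene's TSS (two-sided permutation test, Benjamini-Hochberg over the 24 lists, called at an adjusted p under 0.05). Replicate lists were compared by overlaps of at least 1 bp, with 1000 random placements of replicate 1's peaks (one-sided permutation test).

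The Giant site TTACGTAA with at most 1 mismatch, and 22 other fixed motifs, were sought on both strands within 100 bp of each summit and of a position 1000 bp away on a random side (exact McNemar test, two-sided, Benjamini-Hochberg over 23 motifs). Sides were drawn once for each set of peaks, so a peak's flank can differ between sets. All 7-mers were compared between summit windows and both flanks (Fisher's exact test, two-sided, Benjamini-Hochberg). Fisher's test treats windows as independent, although a summit and its flanks belong to the same peak and some summits lie close together. As an alternative control, 1 random window per peak was drawn in the same 2% class of GC content and the same promoter or non-promoter class. Shares of peaks per arm were compared with arm length (exact binomial test, two-sided). Shares of peaks have 95% Wilson intervals.

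The genes and sequences named were set by a rule written before the data were examined. They were gt, the 20 pooled peaks of highest signal that overlapped a peak of both replicates, every gap and pair-rule gene, and up to 4 genes with the strongest peaks in each other list. The rule also took the 5 motifs of largest ratio and the 10 7-mers of smallest adjusted p. Any other gene is said to have been chosen after its values were seen.

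Alternatives were the conservative list, the pooled peaks above the median signal, each replicate's own list (leaving out the other replicate), other windows and distances, other overlap rules and other backgrounds. After the data were seen, alternatives were added that left out peaks within 300 bp of a stronger peak, that used an IDR of 0.05, that split the Giant site by promoter position, and that measured the correlation among regions below the threshold. The median signal of ranked regions around gt, compared with random main-arm windows (one-sided permutation test), was added in the same way. The list test, the site test and the 7-mer scan were tested on simulated data. A gap list with 60% of its members given peaks was recovered in 3 of 20 simulations and the ribosomal protein list in 20 of 20. With nothing planted, the list test made 0 calls. Of 40 7-mers planted in 5% of 1825 windows, 39 were recovered, and of 40 planted in 2%, 15. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.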

Results

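Sites recovered by anti-GFP chromatin immunoprecipitation were mapped in 2 biological replicates of whole embryos 0 to 18 h old. The labels describe transgenic flies that express an eGFP fusion of Giant. Giant is a basic leucine zipper (bZIP) repressor encoded by the gap gene gt, which patterns the anterior-posterior axis of the early embryo. The authors' pooled list held 1861 peaks, 1825 of them on the main chromosome arms of dm6, with a median width of 356 bp. The lists of replicates 1 and 2 held 1163 and 1100 main-arm peaks. Read depth is unknown, since the files list peaks without read counts. The series has no second group, so the replicates were compared with each other and the pooled peaks with the genome.

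The strongest sites were shared by the replicates. The promoter of Ugalt, a UDP-galactose transporter gene (FBgn0024994, X, 2703729 to 2704030), had the highest signal in the pooled list (1211) and ranked 1 in both replicates, and the promoter of CG14100 (FBgn0036889, 3L, 19590477 to 19590767, signal 1141) ranked 2 in both. The peak at ph-p, a Polycomb group gene (FBgn0004861, X, 2137205 to 2137521, signal 938), ranked 3 in both. Of replicate 1's peaks, 736 of 1163 (63.3%) overlapped a peak of replicate 2, and 767 of 1100 peaks of replicate 2 (69.7%) overlapped one of replicate 1. Random placements of replicate 1's peaks gave 0.458% on average (one-sided permutation p = 0.001, the smallest that 1000 placements allow). Of the pooled peaks, 752 (41.2%) overlapped a peak of both replicates, with a median signal of 153.0, and 476 overlapped none, with a median signal of 68.6.

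The order of signals was compared across regions paired between the replicates. Across 146259 paired main-arm regions, most of them below the threshold, the Spearman correlation of the paired signals was 0.214, and across the 5000 regions of highest signal it was 0.339. It was 0.652 across the 1553 regions of the conservative list, which the IDR selects for similar ranks in both replicates. Regions are not independent replicates, so no p is given. Of the pooled list, 78.1% overlapped the conservative list, and of the conservative list, 91.3% overlapped the pooled list. Pooled peaks absent from the conservative list had a median signal of 66.4, against 107.3 for shared ones.

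The locus of gt, the tagged gene, was examined first as a check of the label. No pooled summit was assigned to gt (FBgn0001150, X, 2427113 to 2428967). A single summit lay within 10000 bp of the gene, in intergenic sequence nearest to CG32797 (X, 2418534 to 2418889), 8401 bp from gt, with a signal of 79.6 and rank 1172 of 1825. Replicate 2 alone had 3 summits in this window and replicate 1 had 0. The ranked pooled list held 26 regions there, or 11.9 per 10000 bp, against 10.9 ± 3.79 (SD of 10000 random X windows, two-sided permutation p = 1). The signal of these regions was raised, a measure chosen after the data were seen. Within 40000 bp of gt the median signal was 1.40 times that of random main-arm windows in replicate 1 (one-sided permutation p = 0.00212) and 1.34 times in replicate 2 (one-sided permutation p = 0.00323). Within 10000 bp it was 1.51 times in replicate 1 (one-sided permutation p = 0.00911) and 1.26 times in replicate 2 (one-sided permutation p = 0.102).

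**Figure D1:**
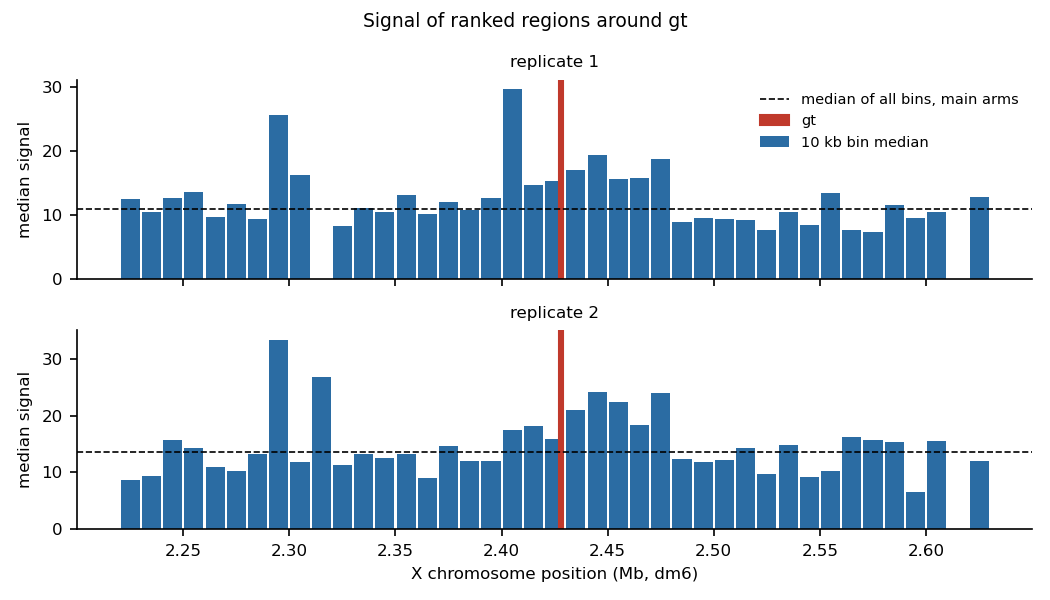
Median signal of ranked regions in 10 kb bins of the X chromosome around gt in each replicate (bars), with the median of all main-arm bins (dashed line, 10.9 in replicate 1 and 13.6 in replicate 2) and gt in red. Bins with fewer than 3 regions are blank, and bins from 2400001 to 2480000 lie above the dashed line in both replicates.

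Pooled peaks concentrated at promoters. Of the 20 strongest peaks shared by both replicates, 15 lay at promoters, 4 in introns and 1 in intergenic sequence. The promoters included those of px, mRpL41 and mRpL23 (mitochondrial ribosomal proteins), CG7601, Tcs5, Art3 (an arginine methyltransferase), Chro (a chromodomain protein of interbands), CG18549, CenG1A, CG5611, CG1888 and PNPase (a mitochondrial RNA-degrading enzyme), with signals from 567.9 to 824.3. The intronic peaks were nearest to CG11050 (828.1), Adf1 (664.9), HmgZ (631.5) and CG32772 (616.3), and the intergenic one lay 11911 bp from CG13323 (610.0). Promoters held 776 of 1825 summits (42.5%, interval 40.3 to 44.8%), against 11.6% of random positions (adjusted permutation p = 0.0028). CDS held 1.64% against 13.9%, 3' UTR 0.658% against 4.48%, introns 34.8% against 39.8% and intergenic sequence 17.6% against 27.9%, all lower with the same adjusted permutation p. The promoter share was 56.7% among the 457 strongest peaks and 29.4% among the 456 weakest (two-sided Fisher's exact p = 7.32e-17), a split chosen after the data were seen.

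**Figure D2:**
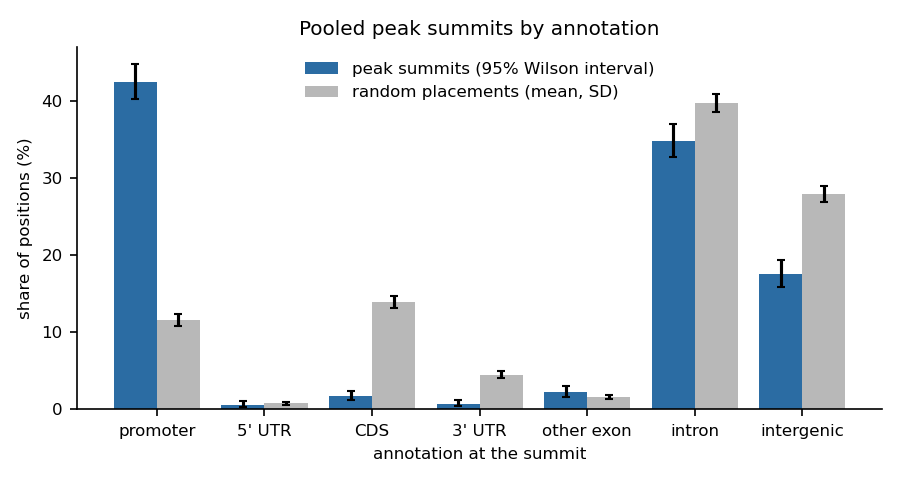
Share of pooled summits in each annotation class (blue, with 95% Wilson intervals) beside the mean of 1000 random placements (grey, with their SD). Promoters hold 42.5% of summits and 11.6% of random positions.

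The X chromosome, which carries gt, held 17.6% of peaks and 17.6% of main-arm sequence (321 peaks, adjusted exact binomial p = 1). The 35 pooled peaks on scaffolds assigned to X, and the sequence of those scaffolds, were outside this comparison. Arm 2L held more than its share (20.9% against 17.6%, adjusted exact binomial p = 0.00084). Chromosome 4 held 1 peak, or 0.0548% against 1.01% (adjusted exact binomial p = 2.52e-06). Regions below the threshold were as scarce on chromosome 4 (0.0656%), and against them its share did not differ (adjusted exact binomial p = 1). Arm 3R was lower only against those regions (22.4% against 25.7%, adjusted exact binomial p = 0.00325).

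Genes of the anterior-posterior segmentation hierarchy, the known field of action of Giant, were not called as carrying more peaks than matched genes. None of 7 gap genes had an assigned pooled peak, where 1.37 were expected (adjusted permutation p = 1). In replicate 2's list alone, 1 of 7 had a peak (0.927 expected). The nearest pooled summits lay 25210 bp from hb, 34783 bp from tll, 48702 bp from hkb, 94223 bp from knrl, 103226 bp from kni and 163960 bp from Kr. Among 9 pair-rule genes, only slp2 had one (expected 1.72, adjusted permutation p = 1), an intergenic peak 4337 bp from its TSS (2L, 3832452 to 3832598, signal 250.2) that ranked 188 in replicate 1 and 116 in replicate 2. This summit was also the nearest to slp1, at 6828 bp. The nearest summits to ftz, prd, odd, eve, run, hry and opa were at 17480, 17667, 18190, 19390, 35391, 45313 and 157505 bp. Lists of this size usually miss even a large difference: with 60% of the members given peaks, the gap list was called in 3 of 20 simulations and the pair-rule list in 4 of 20.

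Other patterning lists were not called either. Segment polarity genes had 4 of 10 with a peak (ptc, nkd, wg and gsb, expected 1.66, adjusted permutation p = 0.556), head gap genes 2 of 5 (cnc and ems), Hox genes 1 of 8 (Antp) and maternal and terminal genes 1 of 8 (bcd, at its promoter, signal 91.6). The strongest peaks at wg, gsb, cnc, ems (signal 15.9) and Antp overlapped no thresholded peak of either replicate. Those at nkd and bcd overlapped a peak of replicate 1 only, and that at ptc overlapped peaks of both. Dorsoventral patterning genes had 8 of 20 with a peak, led by Doc2, ths, tup and dpp, where 3.30 were expected (adjusted permutation p = 0.102). That list passed the threshold with gene bodies in place of the nearest TSS (11 of 20, adjusted permutation p = 0.0368), at 20000 bp (9 of 20, adjusted permutation p = 0.0464) and without matching (8 of 20, adjusted permutation p = 0.0060). It was not called under the other alternatives, with 5 of 20 at 5000 bp, 5 in replicate 2's list alone (adjusted permutation p = 0.650) and 7 in the conservative list (adjusted permutation p = 0.280). Replicate 1's list alone gave 7 (expected 2.33, adjusted permutation p = 0.0864). Peaks above the median signal gave 6 (expected 1.91, adjusted permutation p = 0.111).

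Genes of the cytosolic ribosome carried the clearest excess. Of 92 ribosomal protein genes, 33 had a peak, where 6.49 were expected (ratio 5.09, adjusted permutation p = 0.0048), and 33 of their 34 peaks lay at promoters. The strongest were at RpS27 (3R, 25247443 to 25247611, signal 312.9), RpL34b (249.5), RpL23A (213.0) and RpL7 (194.8), each present in both replicates. The count was 21 in the list of replicate 1 alone (4.83 expected, adjusted permutation p = 0.0048) and 13 in that of replicate 2 alone (4.16 expected, adjusted permutation p = 0.0240). Ribosomal protein peaks were of middling strength, with a median rank of 751.5. Lists of other constitutive complexes were not called: 1 of 48 proteasome genes (Rpn3, expected 3.31, adjusted permutation p = 0.775) and 6 of 65 mitochondrial respiration genes (led by ND-ASHI, ND-24, COX7AL2 and ND-B14.7, expected 5.08, adjusted permutation p = 1) had a peak. The peak at Rpn3 overlapped no thresholded peak of either replicate. Of the respiration peaks named, only that at ND-ASHI overlapped peaks of both.

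Mesoderm regulators formed the other list with more peaks, with 5 of 8 genes against 1.20 expected (ratio 4.15, adjusted permutation p = 0.0336). The strongest assigned peaks were an intronic peak at zfh1 (3R, 30781719 to 30781825, signal 230.8) and a promoter peak at tin (3R, 21378571 to 21378926, signal 201.4), the heart determinant, followed by peaks at Mef2 (122.3) and bin (99.5). The peak at bin overlapped a thresholded peak of replicate 2 only. A stronger summit (signal 400.0), 1071 bp from a Mef2 TSS, was nearer to Pal1 and was assigned to it. The call was lost in the list of either replicate alone, each with 4 of 8 genes, in the conservative list, with 3 of 8, among peaks above the median signal, with 4, at 5000 bp, with 4, and with gene bodies, with 5 (adjusted permutation p from 0.0792 to 0.581). Expected counts were 0.840 in replicate 1 alone, 0.788 in replicate 2 alone and 0.684 above the median signal. They were 1.06 in the conservative list, 1.21 at 5000 bp and 1.91 with gene bodies. Chemoreceptor genes, which are silent in most embryonic tissue, had fewer peaks: 2 of 119, Gr93a and Gr89a, against 10.6 expected (ratio 0.188, adjusted permutation p = 0.0288), with 1 gene in replicate 2's list and 2 in replicate 1's list, neither called. The call was also lost among peaks above the median signal and at 5000 bp.

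The remaining lists were not called against matched genes. Ecdysone and ring gland genes had 5 of 15 with a peak (expected 2.48, adjusted permutation p = 0.556), led by the nuclear receptor genes Hr3 (an intronic peak of signal 462.0), Hr4 (277.6), Eip75B (137.5) and EcR (102.8). Glial genes had 2 of 6 (moody and pnt), heat shock genes 2 of 14 (Hsp27 and Hsp83) and cuticle genes 2 of 70 (Cpr76Ba and Cpr49Ah). Single genes had a peak among neuroblast (grh, 1 of 13), neuron (elav, 1 of 11), muscle (sls, 1 of 11), germline (ovo, 1 of 9) and fat body and gut genes (Lsp1beta, 1 of 24). The strongest peaks at pnt, Cpr49Ah and ovo overlapped no thresholded peak of either replicate. Those at EcR and Lsp1beta overlapped a peak of replicate 1 only, and those at the other genes named here overlapped peaks of both. No peak was assigned to the 6 cellularization, 6 endoderm or 6 tracheal genes.

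**Figure D3:**
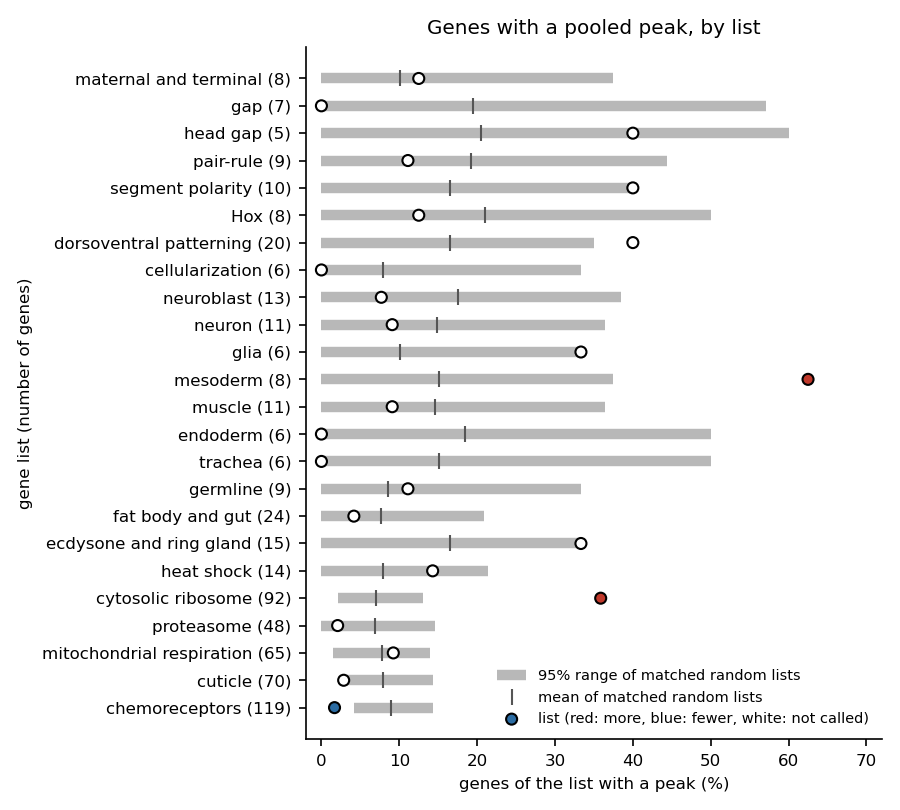
Share of each list's genes with a pooled peak (circles), with the mean (tick) and 95% range (grey bar) of matched random lists. Cytosolic ribosome and mesoderm genes lie above the range and were called, and chemoreceptor genes lie below it.

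The sequence that Giant recognises was more frequent at summits than in flanks, but not than in windows matched on GC content and promoter class. A site within 1 mismatch of TTACGTAA lay within 100 bp of 170 summits (9.32%, interval 8.07 to 10.7%) and in 105 flank windows (5.75%; exact McNemar p = 5.25e-05, adjusted p = 0.000604). Summit windows averaged 38.2% GC and flanks 42.9%. Windows matched on GC content and promoter class held 177 sites (9.70%; exact McNemar p = 0.730). The flank comparison was also split by promoter position after the data were seen, with sides drawn anew. The site lay at 91 of 776 promoter summits and in 55 flanks (exact McNemar p = 0.00256). Outside promoters it lay at 79 of 1049 summits and in 65 flanks (exact McNemar p = 0.265). The 2 classes were not tested against each other. The permuted site TAACGTTA, of the same composition, was also more frequent at summits than in flanks (145 against 102, ratio 1.42, adjusted exact McNemar p = 0.0347), with ratios from 1.09 (matched windows) to 1.5 (replicate 2 alone) and no call under the alternatives, while the permuted site ATTCGAAT was not called (238 against 239). Without a mismatch the Giant site was found at 0.384% of summits and in 0.110% of flanks (exact McNemar p = 0.180).

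The Giant site was more frequent in the 456 strongest peaks (58, 12.7%) than in the 456 weakest (25, 5.48%; two-sided Fisher's exact p = 0.000195). Windows matched to the strongest peaks held 49 sites (10.7%; exact McNemar p = 0.386). The difference was 7.24 percentage points in all peaks, 6.70 within promoter peaks (Fisher's exact p = 0.0561) and 4.58 within other peaks (Fisher's exact p = 0.0822). These splits were chosen after the data were seen. They hold fewer peaks, so their lack of significance does not show that promoter position accounts for the difference.

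Among the other fixed motifs, promoter elements stood out. TATCGATA, bound by DREF and BEAF, was present at 48 summits and in 8 flank windows (ratio 6, adjusted exact McNemar p = 1.08e-06), 45 of the 48 at promoters, and exceeded the 19 matched windows (adjusted exact McNemar p = 0.00568). The M1BP motif GGTCACACT was present at 15 summits against 2 flanks (adjusted exact McNemar p = 0.0180), but not more than in matched windows (8, adjusted exact McNemar p = 0.690). It was not called in the list of replicate 1 (ratio 2.60) or replicate 2 (ratio 3.50) alone. The call rests on a single draw of flank sides: split by promoter position, which drew sides anew, 2 flanks held the motif at promoters and 3 elsewhere. The Su(Hw) motif was at 8 summits against 5 flanks (adjusted exact McNemar p = 1). Motifs of Zelda, Bicoid, Hunchback, Kruppel, Knirps, Caudal and Tailless were not called against flanks. The GAGA factor motif was not called in the 100 bp windows against flanks, but was lower within 50 bp of summits (ratio 0.392, adjusted exact McNemar p = 0.00349) and higher within 200 bp (ratio 1.64) and against matched windows (ratio 1.80). CAGCTG was called as higher in those last comparisons (ratios 1.23 and 1.496). Against matched windows, Caudal (ratio 0.801) and Stat92E (ratio 0.712) motifs were called as lower.

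The scan of all 7-mers found a sequence with a CAGTG core. Against flanks, 503 of 8192 7-mers were more frequent at summits and 469 less frequent. The 10 with the smallest adjusted p comprised 6 of only A and T (TTTAAAA, TTAAAAA, ATATTAA, AAAATAT, TAAAATA and TATTAAA) and 4 with CAGTG on a strand (ACAGTGG, CAGTGTA, CACTGAG and CACAGTG). ACAGTGG lay at 188 summits (10.3%) and in 2.77% of flank windows (ratio 3.72, adjusted Fisher's exact p = 4.79e-26), and CAGTGTA at 145 summits (ratio 4.75, adjusted Fisher's exact p = 3.68e-25). Against matched windows the number of more frequent 7-mers fell to 67, 49 of which were also called against flanks, and 21 of the 67 held CAGTG, as 48 of all 8192 do. ACAGTGG then had a ratio of 6.48 (adjusted Fisher's exact p = 2.14e-27) and CACTGAG one of 6.29 (adjusted Fisher's exact p = 5.18e-18). Of the A and T 7-mers, TTAAAAA, TAAAATA and TATTAAA were no longer called.

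**Figure D4:**
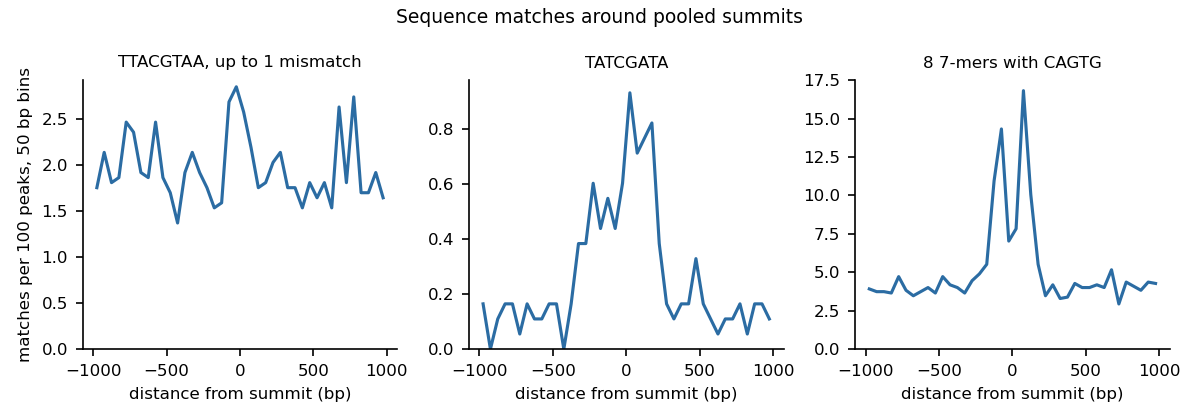
Matches per 100 peaks in 50 bp bins around pooled summits for the Giant site, TATCGATA and 8 7-mers with CAGTG. The 8 7-mers were chosen on peaks of arms 2L, 2R and 4 and are plotted for arms 3L, 3R and X, where they reach 16.8 matches per 100 peaks beside the summit. Their CAGTG core was found in the scan of peaks on all arms.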

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

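The tests of base composition, of promoter position, of the tagged gene, of an IDR of 0.05 and of other constitutive promoters were chosen only after the result was seen, and the others before.

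Peaks outside the main arms form a signal in data that the comparisons left out. The pooled list held 36 such peaks on 28 sequences, 1 of them on Y and 35 on scaffolds assigned to X without a position. Their median signal was 82.0, against 93.7 on the main arms. The authors' thresholded list left out 114 pooled regions past the IDR threshold, 67 on the main arms and 47 elsewhere, with signals up to 1176. The strongest on the main arms, chosen after their values were seen, lay in introns nearest to cbt (2L, 480937 to 481234, signal 882.3) and Lk6 (3R, 11760940 to 11761168, signal 576.7).

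Of 16 gap and pair-rule genes, 1 had a peak, which was not called as fewer than at matched genes. Flies carrying a tagged gene from elsewhere in the genome stay open: the median signal within 40000 bp of gt lay at the 99.7th percentile of random windows in replicate 2 (one-sided permutation p = 0.00323), but within 10000 bp at the 89.8th (one-sided permutation p = 0.102), and a raised stretch does not need a transgene. Binding too weak for the threshold also stays open: at an IDR of 0.05, 5 of 9 pair-rule genes (2.94 expected, adjusted permutation p = 0.667) and 1 of 7 gap genes (2.33 expected) had a peak, and the strongest region below the threshold at these 16 genes had a median percentile of 63.2 among matched genes, within the 27.9 to 71.5 of random lists (one-sided permutation p = 0.123). Peaks beyond the assignment distance also stay open, since 2 of the 16 genes, slp2 and ftz, were nearest to a summit at up to 20000 bp where 2.90 were expected, while the summits within that distance of slp1, gt, prd, odd and eve were nearer to other genes. No biological explanation, such as dilution of early stages in the 0 to 18 h collection, was tested.

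The CAGTG core came from the scan of all 1825 peaks. The 7-mers with it were weighed with 8 of them, chosen on arms 2L, 2R and 4. They were measured on 1124 peaks of arms 3L, 3R and X, which that scan had included. Base composition alone does not account for them, since 36.2% of summits held 1 or more against 10.8% of matched windows, a difference of 25.4 percentage points (exact McNemar p = 4.33e-44). A general promoter sequence does not either: outside promoters the difference was 30.05 percentage points (41.0% against 10.9%, exact McNemar p = 4.59e-33). Copies of a transposable element are argued against by the 0.491% of these windows that touched an annotated element, and by the 36.2% against 10.7% that stayed without such windows. A sequence-specific protein, tagged Giant or another recovered with it, may be the source. This is a hypothesis drawn from the same libraries, and no biological explanation was tested.

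The excess at ribosomal protein genes was set against a general recovery of constitutive promoters. Only 7 of 113 proteasome and mitochondrial respiration genes (6.19%) had a peak, where 8.39 were expected, against 33 of 92 ribosomal protein genes (Fisher's exact p = 9.18e-08). This argues against equal recovery at all constitutive promoters. The lists were not matched on expression level, so recovery that depends on it was not tested. Whether the CAGTG 7-mers mark these promoters stays open: 15.2% of 33 ribosomal protein promoter peaks held 1, against 30.01% of other promoter peaks (Fisher's exact p = 0.0786). Recovery without the tag was not tested, since no peak list from untagged embryos was analysed here.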

How the results depend on the processing

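The overlap of replicate 1 with replicate 2 (57.95 to 70.6%) and the promoter share kept their direction and side of the threshold under every alternative run for them. The X share (17.6 to 20.2%) was not called under any, and lay just below its background only against regions below the threshold (17.63%). The promoter share ranged from 30.2% (200 bp window, 5.17% at random) to 52.5% (1000 bp window, 20.4% at random). The rank correlation was 0.652 in the thresholded regions, 0.339 in the top 5000 and, added after seeing the data, 0.187 below the threshold. At 50% reciprocal overlap, 75.6% of the pooled list was shared with the conservative list. The number of lists with more peaks was 1 in place of 2 (ribosomal proteins alone) in the conservative list, above the median signal, at 5000 bp, at an IDR of 0.05 (added after seeing the data), and 1 without either replicate. It was 3 at 20000 bp and without matching, where dorsoventral patterning was added, and 2 with gene bodies, where that list replaced mesoderm. The Giant site share of 9.32% fell below its control of 9.70% with matched windows, which share the GC content and promoter class of summits but lie elsewhere. It was 0.384% without mismatches, where few sites are left. Its difference by rank was 3.07 points above the median signal and 0.877 points without mismatches (not significant), 6.70 within promoters and 4.58 outside (added after seeing the data). Enriched 7-mers numbered 67 with matched windows. Summits near gt numbered 0 to 3 with a replicate left out and 3 within 20000 bp. For motifs not called against 100 bp flanks, GAGA factor turned to a ratio of 1.64 with 200 bp windows and 1.80 with matched windows, and Caudal to 0.801 with matched windows. The cause was not tested except where stated. With peaks beside a stronger one left out, added after seeing the data, the M1BP motif (ratio 2) and the permuted site TAACGTTA (ratio 1.40) were not called. The flank sides differed in that set too, so the lost calls cannot be put down to the peaks left out. For single lists under the alternatives, 226 values kept their side of the threshold, 11 lost a call and 3 gained one; for single motifs, 154 kept it, 15 lost a call and 4 gained one in the same direction. Depth is unknown, so its limit could not be set.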

Other observations

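All measures in this part were chosen after the data were seen.

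Promoter peaks were concentrated at divergent promoters, where start sites on opposite strands lie within 500 bp of each other. Of 776 promoter peaks, 287 (37.0%) lay there, against 15.4% of promoter sequence (exact binomial p = 1.21e-48).

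Signal around gt was raised in a block. The longest run of 10000 bp bins above the 95th percentile in replicate 1 was on X from 2430001 to 2480000, 5 bins long, where the next longest run on the main arms had 3. It begins 1034 bp from gt and covers tko, z, boi and part of trol. That start is set by the bin grid and the percentile cut. The bins from 2400001 to 2430000, the last of which holds gt, also lay above the median of all bins in both replicates. For the bin with gt the values were 15.3 against 10.9 in replicate 1 and 15.8 against 13.6 in replicate 2. In replicate 2, which was not used to find the block, the block's median signal was 22.2, or 1.65 times that of random windows (one-sided permutation p = 0.00071). Replicate 2's own longest runs had 3 bins, and 1 of its 3 such runs lay in this block, from 2430001 to 2460000. Another, on 2R from 13560001 to 13590000 and away from gt, was raised in replicate 1 too (ratio 1.34, one-sided permutation p = 0.0194). Extra copies of the stretch beside gt from the tagged transgene are a candidate explanation that stays open: signal within 40000 bp of gt lay at the 99.7th percentile in replicate 2, but the bin that holds gt itself (2420001 to 2430000) lay at the 73.3rd there and at the 94.99th in replicate 1. A bin outside the block, from 2290001 to 2300000, lay at the 99.9th percentile in both replicates, above every bin of the block. The extent of the transgene is not given in the sources used here.

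The 7-mers with CAGTG lay beside the summits more than on them. Of matches within 150 bp of summits on arms 3L, 3R and X, 21.9% were within 50 bp, where an even spread gives 33.3% (165 against 589 matches, exact binomial p = 6.19e-12). The 589 farther matches lay in 447 peaks and 7-mers can overlap, so matches are not independent and the p overstates the evidence. The share was 22.6% at promoters and 21.5% elsewhere. Matches on both sides, 50 to 150 bp from the summit, were present at 107 of 1124 peaks.

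Some pooled peaks were weak neighbours of strong ones. Of 1825 peaks, 97 had a summit within 300 bp of a stronger peak's summit, with a median signal of 9.58 against 96.7 for the others, and they included 82 of the 84 peaks with a signal below 30.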
